A study of Arabidopsis thaliana with 5 samples.

How the data were processed

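RNA from 12-day-old whole seedlings of Arabidopsis thaliana was measured on 1-colour Agilent expression arrays, 2 of wild type and 3 of the Atino80-5 mutant. The group and the replicate number of each array were taken from its label. Per the labels' protocols, the seedlings were grown on MS medium in long days, and total RNA was labelled with Cy3 as cRNA. The labels do not say whether the arrays of a genotype held separately grown seedlings.

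The deposited scanner files hold, per spot, an intensity that the scanner software had background-subtracted and detrended within each array, per the file headers, with no scaling between arrays. The file headers give Agilent Feature Extraction 10.7.3.1 with the protocol GE1_107_Sep09, while the submitters' processing notes give version 9.1. The 2 sources differ, and the headers were followed for the columns used. The authors' value table holds log2 values. Set against the scanner values, each of its columns correlated with the log2 processed signal of its array at 0.9994 or more across probes, and the columns shared a 75th percentile of 12.15. It was read as the quantile normalized log2 processed signal, not centred per gene. The column medians were 9.6208 and 9.6213 for wild type and 9.6216, 9.6213 and 9.6213 for Atino80-5. This table has no direction of its own, since each column is a single sample, and it served as an alternative only.

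The 1417 control spots and the 7 to 14 outlier-flagged spots of each array were left out, which leaves 43603 probes. No probe spot was saturated. The log2 processed signal of each array was scaled by subtracting its 75th percentile, and spots of the same probe were averaged. A probe was kept if it was well above background on at least 2 of the 5 arrays, whatever the genotype, which left 35190 probes. Each array's accession column was matched to the RefSeq gene table of assembly TAIR10.1, used here for names only. Of the probes, 34285 matched 1 locus, 9318 matched none and 0 matched several. Of all probes, 19877 had a locus that carries no other gene symbol. Coordinates are not given, because the array's design names another build. A gene with several kept probes was represented by the probe with the highest mean over all arrays. This gave 26649 genes and unnamed transcripts, of which 21241 had a locus and 5408 kept the accession of the array's design. Probe sequences were not used here, so near-identical copies (the LHCB1, RBCS, PDF1.2, SESA, CBF, LTP3 and LTP4, and small heat shock protein genes) could share signal, and their values are uncertain to that extent.

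Atino80-5 was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 3 residual degrees of freedom per gene and 4.55 with the prior. P-values were adjusted over genes by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was the threshold. Changes are Atino80-5 minus wild type on the log2 scale, with the moderated standard error (SE). The number of arrays limits the precision. Where no array of a genotype was well above background, the change is given as "at least N-fold". This sets the mean of the brighter genotype against the mean, over the dimmer genotype's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal.

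A set of 16 gene lists was fixed before the data were examined, with 393 members in all; 3 members that the reference names differently were left out. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists, with camera at an estimated correlation and fry beside it. Lists of transposable element, chloroplast-encoded and mitochondrion-encoded genes, defined by description or locus, found 0 genes under the names used here. Further lists were added later, for the closing section: root-abundant, seed-abundant, early touch and wound response, iron deficiency, nitrate, cytokinin, gibberellin, glucosinolate, dawn-phased and dusk-phased genes. The dawn-phased and dusk-phased lists were written after the values of the circadian clock list had been seen, and the other 8 before any value of a gene was looked at.

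The genes named in the text were set by a rule fixed before the data were examined. It names INO80, then the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with a gene symbol, no overlap between genotypes and the brighter genotype well above background on all its arrays, and then up to 4 members of each list with the smallest p. Any other gene named was chosen after its values were seen.

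The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter requiring all 5 arrays, the mean of a gene's probes, a trended and robust eBayes, array weights, the slide as a block, the replicate number as a block, the authors' value table, a 2-fold minimum, and leaving out each array. Holding each gene's probe while an array is left out was added after the data were seen. The scanner files used here have no mean signal column, so normexp was run on the median signal and the median background in place of the planned mean signal. The model was tested on simulated data made from these arrays, over 26649 genes. It recovered 10% of genes changed 1.19-fold, 60% at 1.41-fold, 84% at 2-fold and 92% at 4-fold, and 5.4% of its 130 calls were unchanged genes. Only 50 genes were changed at each size, whereas 57.2% of genes passed the threshold in the data. The adjusted p depends on that share, so these rates hold for the simulation only. Of 20 simulated lists of 20 genes, the 1 that was shifted by 0.5 had an adjusted p of 2.7e-58 with the preset and 0.0155 with the estimated correlation, and 0 of the others were called. In that simulation genes varied independently and no gene outside the shifted list changed, unlike in the data. Figures were drawn with matplotlib 3.10.9.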

Results

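The transcriptome of 12-day-old whole seedlings of the Arabidopsis mutant Atino80-5 was compared with that of wild type. INO80, the gene the mutant is named for, encodes the ATPase of a chromatin remodelling complex. Transcripts were measured on 5 arrays, 2 of wild type and 3 of Atino80-5, and the comparison asked which genes differed between the genotypes. On each array 33703 to 35569 of 43603 probes, or 77.3% to 81.6%, were well above background. The 75th percentile of the processed signal was 4503 and 4494 on the wild type arrays and 4478, 4639 and 4805 on the Atino80-5 arrays. Spots of the 50 probes printed 5 times varied by 3.58% to 4.87% (median CV). Both wild type arrays and Atino80-5 arrays 1 and 2 shared slide 1, and Atino80-5 array 3 was alone on slide 2.

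INO80 (AT3G57300) was covered by 2 probes, which moved in opposite directions. The probe A_84_P20358 gave processed signals of 9438 and 9289 in wild type and of 62.2, 55.0 and 62.9 in Atino80-5. Its level fell by 7.33 ± 0.074 on the log2 scale (SE, 2 and 3 arrays), or 161-fold (adjusted p = 2.1e-05, limma). The probe A_84_P835513 gave signals of 132 and 124 in wild type and of 504, 484 and 490 in Atino80-5, a rise of 1.90 ± 0.058 or 3.74-fold (adjusted p over probes = 5.5e-05). Both probes were well above background on all 5 arrays. Where either probe lies relative to the mutation is not known here, so the fall of the first separates the labelled genotypes, and neither is known to follow the whole transcript. The first probe represents the gene in the counts below; without wild type array 1 or 2 the second became the brighter and the gene's value turned to 1.95 or 1.86. With the mean of its probes the gene fell by 2.72 (adjusted p = 3.8e-05), and with normexp background correction its log2 change was -6.35.

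**Figure D1:**
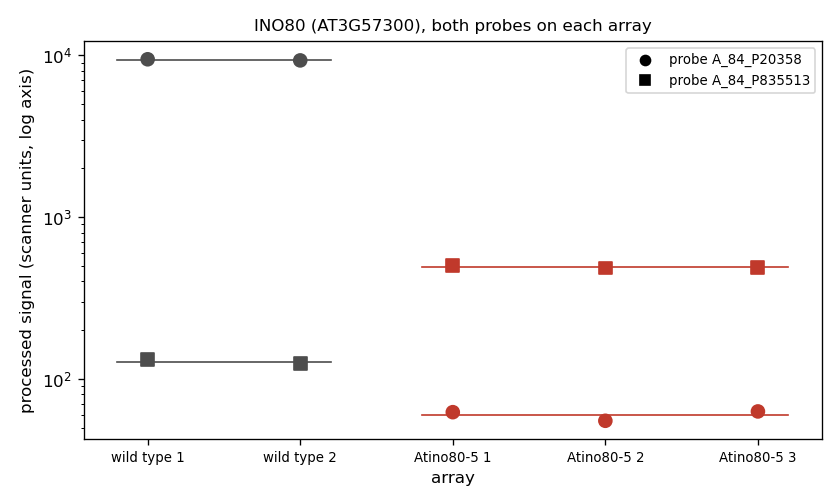
Processed signal (scanner units, log axis) of the 2 INO80 probes on each array, wild type in grey and Atino80-5 in red, with lines at the geometric mean of each genotype. The circles fall from 9438 and 9289 to between 55.0 and 62.9, and the squares rise from 132 and 124 to between 484 and 504.

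Across the transcriptome 8190 genes were higher and 7041 lower in Atino80-5, together 57.2% of the 26649 genes and unnamed transcripts tested. Most changes were small. The median change of the called genes was 1.27-fold, and 87.3% of them changed less than 2-fold. At least 2-fold changes were found for 1229 genes that were higher and 698 that were lower, 4-fold changes for 219 and 175, and 8-fold changes for 49 and 57. With normexp background correction, the counts of at least 2-fold changes were 530 and 424. With each array scaled by its median, 6804 genes were higher and 9043 lower, so that 42.9% of the calls were higher, against 53.8% with the 75th percentile. Within slide 1, which holds 2 arrays of each genotype, 7500 genes were higher and 6382 lower, 1225 and 699 of them by at least 2-fold, and 13269 of these calls had the same direction over all 5 arrays. The slide as a block gave the same counts. The arrays of a genotype correlated at 0.9951 to 0.9964 across genes, and arrays of different genotypes at 0.9799 to 0.9817; genes are not independent replicates. The array values of the genotypes did not overlap for 74.6% of genes, where chance gives 20%. The labels do not say that the arrays came from separately grown seedlings, so the p-values measure only the spread between these arrays, which may be technical.

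The largest fitted increases were ranked among genes with a symbol. Where no wild type array was above background, only a bound is given, and the rank rests on a level that was not measured. ANNAT8, an annexin, was at least 45.0-fold higher (adjusted p = 0.00018), and the 2S albumin gene SESA5 at least 11.0-fold (adjusted p = 2.2e-05). The receptor-like kinase gene PERK12 was 27.3-fold higher, with 1 of the 2 wild type arrays above background. The cytochrome P450 gene CYP82C2 was at least 5.30-fold higher, the defensin-like gene LCR67 at least 5.95-fold, and the transcription factor genes ddf2 and MYB104 11.3-fold and at least 2.78-fold. The seed storage genes CRU2 and SESA3 were at least 3.76-fold and 4.42-fold higher. Without Atino80-5 array 1 another probe, A_84_P68434, became the brightest of SESA3, and the gene lost its call (adjusted p = 0.056); with the first probe held it kept its call (adjusted p = 0.0064). Neither probe was above background on a wild type array, so no fold is given for these. CRU3 rose 10.3-fold (adjusted p = 0.0113), with 1 wild type array above background and a wild type SD of 1.51. Without Atino80-5 array 1, 2 or 3 another probe of CRU3, A_84_P807923, became the brightest and gave log2 changes of 0.40, 0.16 and 0.27, none of which passed the threshold. The same probe stood for the gene, and the call was lost, when probes had to be well above background on all 5 arrays (log2 change 0.27); the mean of its probes rose by 1.82. With the first probe held, the log2 change of 3.37 became 3.45, 3.32 and 3.34 (adjusted p = 0.036, 0.040 and 0.035), and without wild type array 1 or 2 it became 4.43 or 2.304. Holding the probe was chosen after the data were seen, and which CRU3 probe follows the transcript is not known. With normexp background correction these 10 increases were smaller, with log2 changes from 0.61 for MYB104 to 3.19 for ANNAT8, below the bounds where those are given, and each kept its call.

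Of the genes and transcripts that changed at least 8-fold without overlap, 35 had a symbol, 51 only a locus and 19 no locus. After INO80, the largest decreases among those with a symbol were those of LTP4, a lipid transfer protein gene, which fell 86.6-fold (log2 change -6.44 ± 0.14, adjusted p = 3.0e-05), and of HDA2, a histone deacetylase gene, which fell 61.1-fold (log2 change -5.93 ± 0.045, adjusted p = 2.1e-05). LEA7, a late embryogenesis abundant protein gene, was 44.1-fold lower, and LTP3, the close relative of LTP4, 13.7-fold lower. The sucrose transporter gene SUC5 was 13.6-fold lower, with a wild type SD of 1.34; its log2 change of -3.77 became -4.72 or -2.82 without wild type array 1 or 2. The glutamate receptor-like gene GLR1.3 fell 12.9-fold and the P450 gene CYP81D11 11.9-fold. The cell wall invertase gene CWINV5 was at least 9.92-fold lower and the cyclic nucleotide-gated channel gene CNGC18 at least 4.03-fold lower, with no Atino80-5 array above background for either. With normexp background correction the log2 changes of LTP4, HDA2, SUC5, GLR1.3, CWINV5 and CNGC18 were -4.996, -4.78, -2.67, -2.26, -1.506 and -1.03. For CWINV5 and CNGC18 these falls are smaller than the bounds given.

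The list of subunits of INO80 and related remodelling complexes also holds the histone genes HTA8, HTA9 and HTA11, named after their values were seen and not called. Of its 16 measured genes, 4 were higher, 5 lower and 7 not called (4 and 5 adjusted over the list alone). Apart from INO80, the changes were below 1.4-fold. AT4G38495 (EEN) fell by 0.38 ± 0.030 and the actin-related protein gene ARP7 fell by 0.26 ± 0.025. ARP5, another actin-related protein gene, rose by 0.28 ± 0.029. The list did not shift against other genes (camera adjusted p = 0.20).

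Most genes of the DNA damage response and repair were higher by small amounts. Of 40 measured, 30 were higher, 3 lower and 7 not called (31 and 4 adjusted over the list alone), with a median log2 change of 0.24. GMI1, which responds to double-strand breaks, rose by 1.61 ± 0.052 (3.04-fold). KU80, of the end-joining heterodimer, rose by 0.61 ± 0.026, while its partner KU70, named after its value was seen, fell by 0.14; AT4G19130, coding for a replication protein A subunit, rose by 0.56 ± 0.027. PARP2, a poly(ADP-ribose) polymerase gene that damage induces, fell by 0.80 ± 0.049. The list's shift had an adjusted p of 0.00014 with the preset correlation, and adjusted p = 0.16 with an estimated correlation. Of 36 cell cycle and DNA replication genes, 19 were higher, 2 lower and 15 not called (19 and 2 adjusted over the list alone), with a median of 0.12. CYCD3;1, a D-type cyclin, rose by 0.61 ± 0.033, the replication licensing gene CDC6 by 0.55 ± 0.035, CYCB2;3 by 0.54 ± 0.034 and CYCA2;4 by 0.52 ± 0.036. This shift had an adjusted p of 0.0065, and adjusted p = 0.28 with an estimated correlation.

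Phosphate starvation genes were the list with the strongest decrease. Of 20 measured, 16 were lower, 2 higher and 2 not called (16 and 2 adjusted over the list alone), and the median log2 change was -1.15. The signalling gene SPX3 fell by 2.66 ± 0.063 (6.33-fold). MGDC (MGD3), for a galactolipid synthase, fell by 2.22 ± 0.029, SQD2, for sulfolipid synthesis, was 2.83-fold lower, and the phospholipase D gene PLDP2 fell by 1.35 ± 0.025. The genes that rose were the phosphate transporter genes PHT1;1 and PHT1;2, by 0.27 and 0.23, chosen after their values were seen. The shift had an adjusted p of 6.6e-07, and adjusted p = 0.16 with an estimated correlation. In the same arrays root markers rose by a median of 0.66.

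Root hair, endodermis and root meristem markers were higher. Of 17 measured, 16 were higher and 1 lower (16 and 1 adjusted over the list alone), with a median log2 change of 0.66. The expansin genes EXPA18 and EXPA7 of root hairs rose 2.38-fold and 2.01-fold, the root hair cell wall gene PRP3 by 1.08 ± 0.049, and PLT2, a root meristem regulator, by 1.09 ± 0.026 (0.49 with normexp background correction). The gene that fell was SCR, by 0.12, named after its value was seen. Against other genes the shift had an adjusted p of 4.9e-06, and adjusted p = 0.16 with an estimated correlation. Of 29 auxin synthesis, transport and response genes, 19 were higher, 3 lower and 7 not called (19 and 3 adjusted over the list alone), with a median of 0.27. The auxin response genes IAA6, AXR3 (IAA17) and IAA1 rose by 1.18 ± 0.043, 0.64 ± 0.030 and 0.43 ± 0.024, and WES1 (GH3.5), coding for an auxin-conjugating enzyme, by 0.52 ± 0.026. This shift had an adjusted p of 0.0031, and adjusted p = 0.18 with an estimated correlation.

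Photosystem and Rubisco genes were mostly not called. Of 47 measured, 19 were lower, 2 higher and 26 not called (15 and 2 adjusted over the list alone), and the median log2 change was -0.14. The antenna gene LHCA2 fell by 0.37 ± 0.044, and the photosystem I genes PSAE-2 and PSAH-1 fell by 0.34 ± 0.028 and 0.30 ± 0.035. LHCB4.3, an antenna gene induced by strong light, rose by 1.16 ± 0.027. Tested against other genes, the list had an adjusted p of 0.00045, and adjusted p = 0.23 with an estimated correlation. It was lost with quantile normalization (adjusted p = 0.27) and in the authors' value table (adjusted p = 0.28).

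Flowering time genes changed in both directions. Of 25 measured, 9 were higher, 10 lower and 6 not called (9 and 10 adjusted over the list alone). FLC, the main repressor of the floral transition, rose by 1.67 ± 0.036 (3.19-fold). The florigen gene FT fell by 1.73 ± 0.030 (3.32-fold), the floral promoter AGL24 fell 4.94-fold, and FKF1, a light-regulated activator of flowering, fell by 0.64 ± 0.032. The FLC relatives MAF2, MAF3, MAF4 and MAF5, chosen after their values were seen, rose by 0.51, 0.34, 0.50 and 0.55. The median of the list was 0.01 and its mean -0.16, and it did not shift against other genes (camera adjusted p = 0.76). Of 20 circadian clock genes, 7 were higher, 8 lower and 5 not called (7 and 9 adjusted over the list alone). The morning genes LHY, CCA1, RVE8 and RVE1 rose by 1.18 ± 0.043, 0.61 ± 0.027, 0.90 ± 0.047 and 0.90 ± 0.055. The list's median of -0.08 and mean of 0.08 differed in sign, and it did not shift (camera adjusted p = 0.72).

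**Figure D2:**
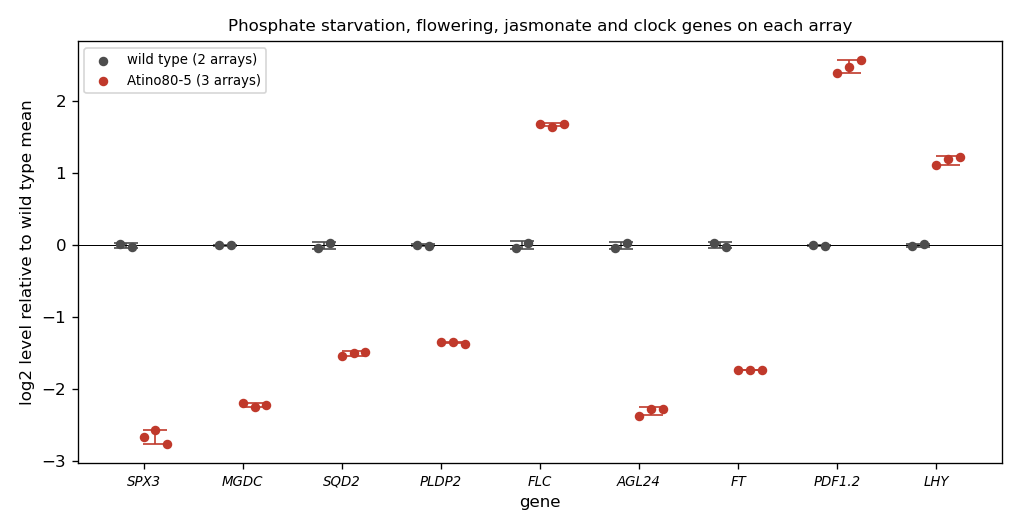
Log2 level of 9 named genes on each of the 5 arrays, relative to the wild type mean, with wild type in grey and Atino80-5 in red; bars are the SD within a genotype. FLC, PDF1.2 and LHY lie above and SPX3, MGDC, SQD2, PLDP2, AGL24 and FT below the wild type arrays on all 3 Atino80-5 arrays.

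Floral organ identity markers were higher in these seedlings. Of 8 measured, 6 were higher, 1 lower and 1 not called (6 and 1 adjusted over the list alone), with a median of 0.87. The organ identity genes AG, SEP1, PI and SHP1 rose by 1.33 ± 0.050, 1.18 ± 0.034, 1.16 ± 0.034 and 1.03 ± 0.047; AG rose by 0.69 with normexp background correction. The gene called lower was AP3, by 0.56, named after its value was seen. The gene not called had the lowest log2 change of the list, -0.657. Camera gave this shift an adjusted p of 0.0116, and adjusted p = 0.16 with an estimated correlation. It was lost with the replicate number as a block (camera adjusted p = 0.060). Of 16 seed maturation and storage markers, 10 were higher, 1 lower and 5 not called (10 and 1 adjusted over the list alone). The median log2 change was 1.67, or 1.05 with the 6 genes that have only a bound set at it. Besides SESA5 and CRU2, the cruciferin gene CRA1 rose by 1.19 ± 0.068 (2.27-fold) and the oleosin gene OLEO1 was at least 1.89-fold higher. With normexp background correction another probe of OLEO1, A_84_P12895, became the brightest, with a log2 change of 0.40, so this value differs in both probe and background. The gene that fell was LEC2, by 0.52, named after its value was seen. The shift had an adjusted p of 0.012, and adjusted p = 0.27 with an estimated correlation. It was lost when probes had to be well above background on all 5 arrays (9 genes left, adjusted p = 0.45).

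Salicylic acid and pathogen defence genes rose. Of 21 measured, 18 were higher, 0 lower and 3 not called (19 and 0 adjusted over the list alone), with a median of 0.61; 0 were lower at an unadjusted p under 0.05 in limma. The transcription factor gene WRKY70 rose by 1.64 ± 0.031, the glutaredoxin gene GRX480 by 1.69 ± 0.046, CBP60G, a regulator of salicylic acid synthesis, by 1.43 ± 0.032 and NIMIN1, whose product binds NPR1, by 0.84 ± 0.036. Against other genes the shift had an adjusted p of 3.7e-05, and adjusted p = 0.16 with an estimated correlation. Of 26 jasmonate genes, 17 were higher, 5 lower and 4 not called (18 and 6 adjusted over the list alone), with a median of 0.31. The defensin genes PDF1.2 and PDF1.2b rose by 2.48 ± 0.058 and 1.46 ± 0.037, and the lipoxygenase genes LOX3 and LOX4 by 1.69 ± 0.025 and 1.002 ± 0.034. The genes that fell were VSP1, AOC1, VSP2, LOX2 and CORI3, named after their values were seen, with log2 changes of -0.53, -0.56, -0.57, -0.57 and -1.09. Tested against other genes, the list had an adjusted p of 0.0052, and adjusted p = 0.16 with an estimated correlation. Of 17 flavonoid and anthocyanin genes, 14 were higher, 0 lower and 3 not called (15 and 1 adjusted over the list alone), with a median of 0.63; 1 was lower at an unadjusted p under 0.05 in limma. The regulator TT8 rose by 1.55 ± 0.062, the anthocyanin enzyme gene DFR by 1.12 ± 0.049, the chalcone synthase gene TT4 by 0.68 ± 0.030 and F3H by 0.59 ± 0.028. Camera gave this shift an adjusted p of 0.00025, and adjusted p = 0.16 with an estimated correlation.

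Heat shock protein genes were lower. Of 15 measured, 11 were lower, 1 higher and 3 not called (11 and 1 adjusted over the list alone), with a median log2 change of -0.38. The small heat shock protein gene ATHSP22.0 was at least 7.13-fold lower. With normexp background correction its log2 change was -1.27, a smaller fall than that bound. AT1G53540 and AT2G29500, also small heat shock protein genes, fell by 2.33 ± 0.075 and 1.98 ± 0.038, and AT5G37670 rose by 0.58 ± 0.045. The shift had an adjusted p of 0.00025, and adjusted p = 0.16 with an estimated correlation. Abscisic acid, cold and drought genes split. Of 27 measured, 13 were lower, 10 higher and 4 not called (14 and 10 adjusted over the list alone). The dehydrin gene RAB18 fell by 2.27 ± 0.038 and the cold-regulated gene COR15A was 4.60-fold lower, while the cold-response activators CBF2 and CBF1 rose by 2.21 ± 0.030 and 2.09 ± 0.042. The median was -0.08, and the list did not shift (camera adjusted p = 0.11).

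**Figure D3:**
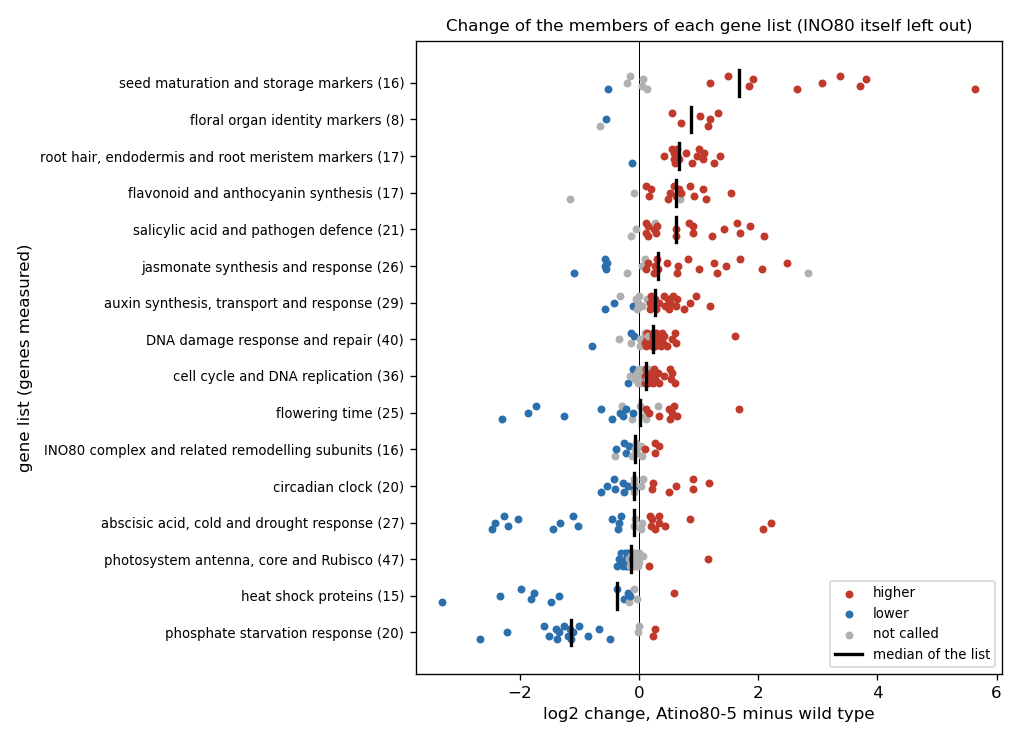
Log2 change (Atino80-5 minus wild type) of each measured member of the 16 gene lists, with the number measured in brackets; red points were higher, blue lower and grey not called, and black bars are the list medians. Medians run from -1.15 for phosphate starvation genes to 1.67 for seed markers; INO80, at -7.33, is left out of the plot.

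Within slide 1, the medians of the 16 lists differed by at most 0.063 from those over all 5 arrays. With the slide as a block, which rests on slide 1 alone, each list stayed on the side of the camera threshold it had over all 5 arrays. By fry, which asks whether a list's genes moved on balance in a direction, all 16 lists passed (adjusted p of 0.022 or less), those that did not shift against other genes included. The list of remodelling subunits holds INO80 itself, and fry was not run without it. None of the list shifts past the threshold with the preset correlation held with an estimated correlation. With an estimated correlation camera takes its p-value from the 3 residual degrees of freedom, and with a preset one from the number of genes. Part of the loss thus comes with the small number of arrays. The size of the correlation alone does not account for the loss in each list. For the salicylic acid genes it was estimated at 0.011, near the preset 0.01, yet the unadjusted camera p rose from 6.9e-06 to 0.021. For the floral markers it was estimated at -0.07.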

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

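The alternatives were fixed before the data were examined, except that of holding each gene's probe when an array is left out, which was chosen after. The counts of 8190 genes higher and 7041 lower stayed within 1.5 times under the alternatives on processing and the slide block (6804 to 8700 higher, 6020 to 9043 lower) and without each array (6310 to 7897 higher, 4875 to 6627 lower); with a 2-fold minimum they were 1229 and 698. With normexp background correction, whose offset shrinks the changes of dim probes, the at least 2-fold counts were 530 and 424. INO80 kept its fall under the 11 alternatives on processing and design, at -2.715 with the mean of its probes, but without wild type array 1 or 2 its value was 1.949 or 1.856, and over the arrays left out it ranged from -7.385 to 1.949. The cause is the rule that takes the brightest probe, which then chose the second probe; with the probe held it was -7.322 or -7.342. Among the gene lists, the photosystem shift was lost with quantile normalization (adjusted p = 0.274) and in the authors' value table (0.2826), and the seed shift when probes had to be above background on all 5 arrays (0.4506), which left 9 of its 16 genes. The cause of the photosystem losses was not tested. With an estimated correlation, each list shift was lost: adjusted p = 0.1581 for DNA damage, heat shock, salicylic acid, jasmonate, flavonoid, phosphate, root and floral genes, 0.1763 for auxin, 0.2344 for photosystem, 0.2675 for seed and 0.2785 for cell cycle genes. The lists lost included that of salicylic acid, whose estimated correlation of 0.011 was near the preset 0.01. Camera with an estimated correlation rests on 3 residual degrees of freedom, so these losses partly reflect the number of arrays. Apart from the floral markers with the replicate block, the other list results kept their side of the threshold. The trended and robust eBayes does not enter the list test, so its list results equal the main ones. Of the 80 named genes besides INO80, 866 of 868 values under other alternatives and 396 of 400 with an array left out kept their call; the exceptions were CRU3 and, without Atino80-5 array 1, SESA3, each where another probe became its brightest one kept. With the probe held, all 400 kept their call. Under the filter requiring all 5 arrays, 67 of the named genes kept their call and 1 lost it, while the others had no probe left and give no value. Probes near background limit the seed markers most.

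With the replicate block over numbers 1 and 2 (4 arrays), 6325 genes were higher and 4900 lower, and the floral marker shift had an adjusted p of 0.05996; apart from that and CRU3, for which another probe was then the brightest, the block changed no call of a list or named gene. The deviations of same-numbered arrays from their group means correlated at 0.038 and 0.005 across genes, which gives no sign of pairing by number. Differences between arrays of a genotype hardly reproduced between 2 probes of a gene (correlation of 0.1881 at most), so these values cannot exclude pairing. A lone wild type array, left by leaving out the other, is assumed to vary like the Atino80-5 arrays.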

Other observations

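The lists in this part were added after the main lists were fixed. Their values had not been seen when they were written, but the dawn-phased and dusk-phased lists were written after the clock genes' values were known. Genes named here were chosen after their values were seen. The test on pairs of probes was chosen after the count of calls was seen, and the other tests before their results.

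Genes of the early response to touch, wounding and elicitors were higher in Atino80-5. All 19 measured were higher (19 adjusted over the list alone), with a median log2 change of 0.98 (camera adjusted p = 4.6e-10 over 10 lists, and adjusted p = 0.13 with an estimated correlation). The transcription factor gene RRTF1 rose by 3.05 ± 0.027, the calmodulin-like gene CML39 by 1.94 ± 0.085 and the zinc finger gene ZAT12 by 1.61 ± 0.030. Of 15 iron deficiency genes, 12 were higher and 2 lower, with a median of 0.48 (adjusted p = 0.0064, and adjusted p = 0.30 with an estimated correlation), in arrays where root markers were also higher. The iron transporter gene IRT1 rose by 0.83 ± 0.052, and the nicotianamine synthase gene NAS1 fell by 1.03 ± 0.036. Of 10 nitrate genes, 8 were lower and 1 higher, with a median of -0.35 (adjusted p = 0.012, and adjusted p = 0.30 with an estimated correlation). HRS1, a regulator of the nitrate and phosphate responses, fell by 1.15 ± 0.040, and the nitrate reductase gene NIA2 fell by 0.69 ± 0.0999.

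Of 19 gibberellin genes, 11 were higher and 4 lower, with a median of 0.32, and the shift did not pass (adjusted p = 0.065). The gibberellin-inactivating GA2OX8 rose by 1.64 ± 0.043 and the biosynthetic GA20OX1 by 1.12 ± 0.035. Of 17 glucosinolate genes, 8 were higher and 3 lower, with changes from -0.90 to 0.98 (adjusted p = 0.20). Of 12 cytokinin genes, 5 were higher and 5 lower (adjusted p = 0.89). Of 9 dawn-phased genes, 5 were higher and 2 lower, with a median of 0.25 (adjusted p = 0.20), and of 10 dusk-phased genes 1 was higher and 5 lower, with a median of -0.09 (adjusted p = 0.22). Neither clock-related list passed the threshold.

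Of the genes tested, 57.2% passed the threshold. The slide that holds Atino80-5 array 3 alone does not account for it, since 13882 genes passed within slide 1, against 15231 over all arrays. A small spread between arrays of a genotype could contribute. The differences between 2 arrays of a genotype correlated at no more than 0.1881 between 2 probes of the same gene over 6126 genes, while the differences between genotypes correlated at 0.84 or more, so that most of the spread within a genotype looks like measurement noise. In 1 of the 10 splits of the 5 arrays into 2 and 3, the real one, 15231 genes passed, and in the highest other split 1 gene; 10 splits are too few for a share under 0.05. An effect of the mutation and a difference between separately handled batches of seedlings remain open.

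Root markers were higher in Atino80-5, and a larger share of root tissue in those samples is a candidate explanation. Of 19 root-abundant genes chosen independently of the fixed list, 15 were higher and 2 lower, with a median log2 change of 0.76 and an interquartile range of 0.4758, within the limit of 0.5 set for a common factor (camera adjusted p = 0.00012, and adjusted p = 0.31 with an estimated correlation). The changes ran from -1.497 to 1.422 with a median SE of 0.0437. The genes thus differed beyond measurement spread, and meeting the limit does not show that they rose by a single factor. The abundant peroxidase and beta-glucosidase genes AT5G17820 and PYK10 rose by 1.05 and 0.63. The genes that fell were WOX5, by 1.497, and TIP2;2, by 0.44, which a root share alone would not lower. A change of gene activity within roots in the mutant was not tested and stays open beside it.

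Seed storage transcripts were higher in Atino80-5, and seeds that had not germinated, or their remains, may have contributed. Of 8 seed-abundant genes chosen independently, 5 were higher and 1 lower, with a median log2 change of 0.5111 (95% bootstrap interval -0.141 to 1.499 over genes; camera adjusted p = 0.33). The prediction was a median of at least 1, and the interval covers it as well as 0, so that this and a change in gene activity in the seedlings cannot be told apart. PAP85 rose by 0.996 and M17 fell by 2.57.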
